A study of Sus scrofa with 33 samples.

How the data were processed

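RNA was measured in 33 biopsies of the right ventricular free wall, taken at 3 times from each of 11 pigs (Sus scrofa). The first biopsy was the baseline. The next came after 120 min of pulmonary banding, a constriction of the pulmonary artery that was used to bring on right ventricular failure. The pigs were then randomised. In the control arm (5 pigs) banding went on for a further 60 min before the last biopsy. The shunt arm (6 pigs) had the same 60 min with a modified Glenn shunt, a connection from the superior vena cava to the pulmonary artery that lets venous blood bypass the right ventricle. Total RNA extracted with TRIzol and purified on RNeasy columns was turned into biotinylated cRNA and hybridised to the Affymetrix Porcine Genome Array, with 1 array per biopsy and no pooling.

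The deposited values are log2 probe set summaries made by the authors with RMA, which corrects the background, quantile normalises the arrays together and summarises the probes of each set. The RMA software, its version and which arrays were normalised together are not given in the sources used here. The values ran from 2.21 to 15.2, and the array medians lay between 6.10 and 6.17. They were used as deposited, with no further scaling, floor or filter. Of 24123 probe sets, 124 control sets were left out of the tests and 23999 were tested. The spiked-in controls were used to look for sets of arrays handled apart.

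Gene symbols came from the platform annotation, which listed 10297 of the probe sets. A single symbol was given for 10069 of them, several symbols for 198, and none for 13732 of those tested. Through their Entrez identifiers, 9961 of the single-symbol probe sets matched a RefSeq entry. A gene was represented by its single-symbol probe set with the highest mean over all arrays, which gave 6765 genes, of which 2261 had more than 1 probe set. No genome build was used, so no positions are given.

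Changes were estimated in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on all arrays at once, with a coefficient for each pig and, within each arm, a coefficient for the biopsy at 120 min and for the last biopsy. This left 18 residual degrees of freedom. Pig was a fixed block because the labels give the same animal at each time. The pairing was checked on the values: after removal of the group means, arrays of the same pig correlated with a median r of 0.395 and arrays of different pigs with a median of -0.115, and 29 of 33 arrays were closest to an array of their own pig. The response to banding was the mean over the 11 pigs of the change from baseline to 120 min. The later change, from 120 min to the last biopsy, and the whole course, from baseline to the last biopsy, were estimated in each arm, and the differences between the arms were tested as interactions. The arms were also compared at baseline, on the 11 baseline arrays alone. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 23999 probe sets, with a threshold of 0.05. Errors of fitted changes are standard errors (SE), and the spread between pigs is given as SD. Confidence intervals are at 95%.

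Lists of genes (21) and of cell type markers (12) were tested with camera of limma at its preset correlation between genes of 0.01, over the 6765 genes, with Benjamini-Hochberg over the 33 lists of each comparison. Lists with fewer than 3 measured genes would not have been tested. Camera with an estimated correlation was run beside it, and so was fry, which asks whether the genes of a list move, on balance, one way and does not compare them with other genes. The count of members past the threshold is given over all probe sets and adjusted over the list alone.

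The genes named were set by rule. For the response at 120 min these were the 12 largest rises and 12 largest falls among genes that passed the threshold and changed in the same direction in every pig. For the other changes within an arm they were the 10 largest of each. For comparisons between arms, the 10 largest differences of each sign that passed were taken. Where fewer than 5 passed, the 5 genes with the smallest p in each direction are given and said not to pass. Up to 4 members of each list, those with the smallest p, could be named as well, and a panel of 19 genes was fixed whatever its values, of which 16 were measured. The groups, tests, lists, naming rule and most alternatives were set before the data were examined. The division of the pigs by array set, and the alternatives that use it, were chosen after the data were seen.

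The alternatives were centring each array on its median, quantile normalisation of the deposited values, no pig block, pig as a random block (duplicateCorrelation, statmod 1.5.0), only the arrays compared, an intensity trend with robust eBayes, the 30% of probe sets with the lowest mean left out, array quality weights, a minimum change of 1.5-fold, 1 probe set per gene, the mean of the probe sets of a gene, and each pig left out in turn. Those added later were fits to 1 array set alone and the array set as a random block at baseline. Splits of the pigs, swapping the biopsies compared or the arms, were counted up to 100 per comparison. The tests run after the result was seen were exact permutation or sign-flip tests, 95% confidence bounds of single genes and a correlation across genes.

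The models were tested on simulated data with the design of the series, 5 draws and 200 changed probe sets per draw. Changes of 2-fold were recovered at 96 to 100% within the arms and over all pigs and at 88.4 to 88.8% in the differences between arms. At 1.5-fold these shares were 76.8 to 94% and 52 to 55.6%. At 1.25-fold they were 24.4 to 67.2% and 6.8 to 8%. False calls made up 3.69 to 6.44% of the calls. The simulated noise was normal and independent between probe sets and arrays, so these shares need not hold for real arrays, whose probe sets vary together. The number of arrays limits the precision: the median half-width of the confidence interval was 0.14 on the log2 scale for the response over all pigs, 0.19 in the shunt arm, 0.21 in the control arm and 0.28 for differences between arms. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.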

Results

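Gene expression was measured on 33 arrays from right ventricular myocardium of 11 pigs, each biopsied at baseline, after 120 min of pulmonary banding and at the end of a further 60 min. There were 6 pigs in the shunt arm and 5 in the control arm, so that each of the 6 groups of arm and biopsy held 6 or 5 arrays. All values are log2 RMA values, and changes are differences of log2 values within a pig. No pigs without banding were biopsied over the same hours, so every change between biopsies includes all that elapsed between them. Arrays measure hybridisation signal and hold no read depth, and their number limits the precision.

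The arrays were alike in distribution, with pairwise correlations between 0.956 and 0.995. The first principal component held 33.2% of the variance and the next 10.5%. On the first component the baseline arrays averaged -28.1 ± 7.86 in the shunt arm and -32.2 ± 3.20 in the control arm (SD, n = 6 and 5 pigs). At 120 min the means were 22.6 ± 11.8 in the shunt arm and -0.598 ± 10.9 in the control arm, and at the last biopsy 31.2 ± 23.0 and 1.92 ± 14.1. The difference between 3' and 5' probe sets of GAPDH, a sign of RNA quality, was 0.76 ± 0.15, 0.72 ± 0.12 and 0.67 ± 0.18 at the 3 biopsies of the shunt arm. In the control arm it was 0.86 ± 0.15, 0.96 ± 0.11 and 0.91 ± 0.20.

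**Figure D1:**
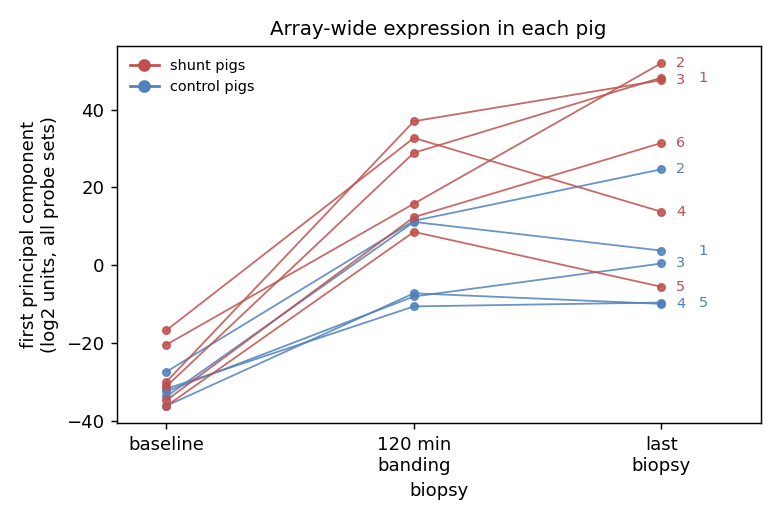
Score on the first principal component of all probe sets (vertical axis, log2 units) at the 3 biopsies (horizontal axis), with a line per pig, numbered at its end, for 6 shunt and 5 control pigs. The baseline arrays averaged -28.1 and -32.2 in the shunt and control arms, and the last arrays 31.2 and 1.92.

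The spiked-in control RNAs divided the arrays into 3 sets by pig. In shunt pigs 1 to 4 (12 arrays) the Dap control gave 3.20 ± 0.08 and BioB 8.22 ± 0.15 (SD over arrays). In shunt pigs 5 and 6 (6 arrays) Dap gave 8.53 ± 0.20 and BioB 5.92 ± 0.12, and in control pigs 1 to 5 (15 arrays) 7.72 ± 0.71 and 9.26 ± 0.35. No set held pigs of both arms. Changes within a pig compare arrays of the same set, but in every comparison between the arms the array set and the arm cannot be told apart.

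The comparison of 120 min of banding with baseline asked what changed as right ventricular failure was brought on. The largest rise was that of PTX3, which encodes the acute-phase pattern recognition protein pentraxin 3. Its transcript rose by 4.30 ± 0.33 (SE, n = 11 pigs), or 19.7-fold, with an adjusted p of 3.36e-09. HSPA6, a strictly stress-inducible heat shock protein of the HSP70 family, rose 16.3-fold (4.03 ± 0.55, adjusted p = 5.87e-06), and CCL2, the chemokine that draws monocytes, 10.6-fold (3.40 ± 0.29, adjusted p = 1.37e-08). CYR61, a secreted matrix-associated protein induced by stretch, rose 9.03-fold (3.17 ± 0.27), the antiproliferative gene BTG2 8.69-fold (3.12 ± 0.29) and the cytokine gene IL6 7.79-fold (2.96 ± 0.43). The other named rises were those of AREG, a ligand of the EGF receptor (7.41-fold), the metallothionein MT-2B (6.50-fold), the immediate early gene IER3 (6.30-fold), XIRP1, an actin-binding protein of the intercalated disc (5.68-fold), PLIN2, a coat protein of lipid droplets (5.60-fold), and GADD45A, which is induced by DNA damage and growth arrest (5.35-fold). All 12 were higher in 11 of 11 pigs.

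Falls were smaller. FPGT, an enzyme of fucose salvage, fell by 1.39 ± 0.12, so that it was 2.62-fold lower (adjusted p = 1.17e-08), and CEP85, a centrosomal protein, fell by 1.39 ± 0.16. The cold-inducible RNA-binding protein gene CIRBP was 2.15-fold lower (-1.10 ± 0.10, adjusted p = 3.27e-08). The septin gene SEPT8, which had the smallest adjusted p of all probe sets (2.83e-11), fell by 0.98 ± 0.05. PPP1R3B, which targets protein phosphatase 1 to glycogen, fell by 0.97 ± 0.11. MAP10 (-1.17 ± 0.09), the methyltransferase METTL18 (-1.08 ± 0.08), FAIM, an inhibitor of Fas-induced apoptosis (-1.05 ± 0.12), the zinc finger gene ZNF382 (-1.04 ± 0.09), RWDD3 (-0.99 ± 0.11), RBM12B (-0.96 ± 0.13) and BANP (-0.94 ± 0.08) completed the 12. Each was lower in 11 of 11 pigs.

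**Figure D2:**
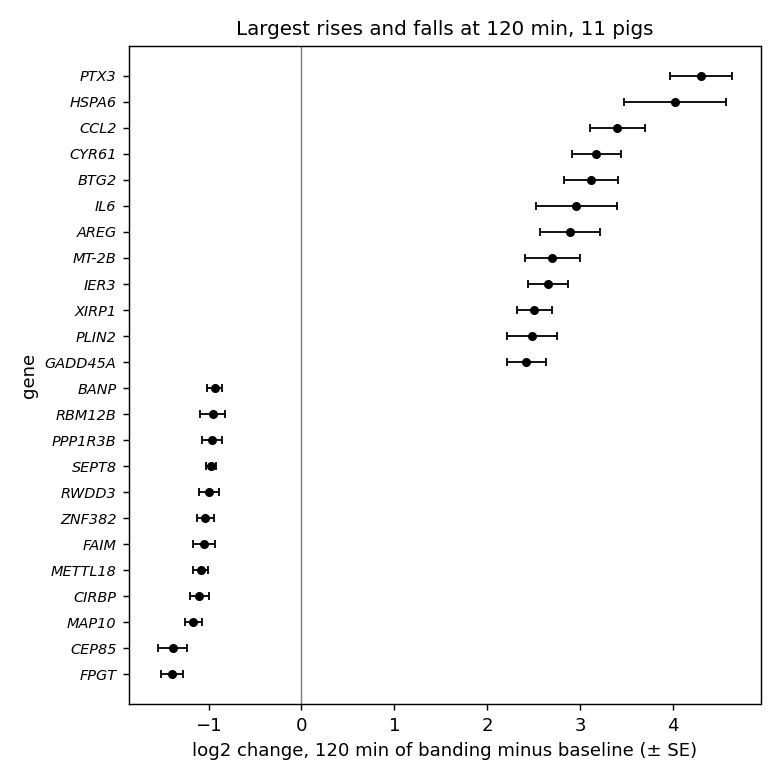
Log2 change from baseline to 120 min of banding (horizontal axis, points with SE bars, n = 11 pigs) of the 12 largest rises and 12 largest falls (vertical axis, genes). The rises run from 2.42 for GADD45A to 4.30 for PTX3 and the falls from -0.94 for BANP to -1.39 for FPGT.

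In limma 6964 of 23999 probe sets (29.0%) passed, 2794 higher and 4170 lower. Among changes of at least 1.5-fold the balance was the other way, with 677 higher and 441 lower, and at 2-fold 250 were higher and 43 lower. The calls covered 2291 genes, 887 higher and 1404 lower, and 2336 of the probe sets called changed in the same direction in every pig. The fits to each array set alone called 2369 probe sets in shunt pigs 1 to 4, 1790 in control pigs 1 to 5 and 454 in shunt pigs 5 and 6. Of the 2291 genes, 2255 (98.4%) had the same direction of change in all 3 sets. They had been called on the mean of these same pigs, which favours a shared direction, so that share is no independent replication. Over all 6765 genes, called or not, 2 sets at a time had the same direction in 74.7 to 78.9% of genes.

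Of 33 lists, 14 passed camera, 12 higher and 2 lower. With an estimated correlation between genes only the p53 list passed, and by fry 17 did. Lists shared members: 11 of 23 stretch, 11 of 19 glucocorticoid-induced, 15 of 26 leukocyte adhesion, 12 of 19 sarcomere and 8 of 31 cytokine genes stood in another list too, and none of the ribosome biogenesis or neutrophil genes did. The immediate early genes, transcribed within minutes of a stimulus, rose most: 18 of 21 measured members rose and none fell, and 18 rose adjusted over the list alone. The list mean was 1.35 ± 0.55 (SD over pigs), an adjusted p of 7.66e-12 by camera and an adjusted p = 0.149 with an estimated correlation. MYC, the growth-promoting transcription factor, rose by 2.30 ± 0.21 (SE). Of inflammatory cytokines and NF-kB targets, 21 of 31 rose and none fell (22 adjusted over the list alone), with a mean of 0.95 ± 0.41 (adjusted p = 1.74e-10, and adjusted p = 0.149 with an estimated correlation). They included the leukocyte adhesion molecule ICAM1 (1.77 ± 0.22) and the receptor gene IL4R (1.29 ± 0.16). Of the IL-6/STAT3 acute-phase targets, 8 of 15 rose and none fell, as many as when adjusted over the list alone, among them STAT3 itself (0.99 ± 0.11) and CEBPD (1.09 ± 0.11). That list averaged 0.66 ± 0.19, with an adjusted p of 1.13e-05, and an adjusted p = 0.143 with an estimated correlation.

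Of heat shock proteins and chaperones, 17 of 29 rose and 3 fell (17 and 4 adjusted over the list alone), with a list mean of 0.55 ± 0.31. The adjusted p was 1.18e-05, and adjusted p = 0.401 with an estimated correlation. The co-chaperone BAG3 rose by 1.56 ± 0.21, HSPB8 by 1.30 ± 0.15 and the small heat shock protein CRYAB by 0.54 ± 0.06. The p53, cell cycle arrest and apoptosis list had 11 rises and 1 fall among 23 members, as many as when adjusted over the list alone. Its mean was 0.53 ± 0.11 and its adjusted p 1.78e-05, with adjusted p = 0.0492 with an estimated correlation. TNFRSF12A, the receptor of the cytokine TWEAK, rose by 1.98 ± 0.14, PMAIP1 by 1.36 ± 0.16 and GADD45G by 1.23 ± 0.13. In the ribosome biogenesis and translation list 13 of 25 rose and none fell (15 adjusted over the list alone), with a mean of 0.36 ± 0.12 and an adjusted p of 2.77e-06, and adjusted p = 0.290 with an estimated correlation. Its members included the helicase of translation initiation EIF4A1 (1.36 ± 0.11), the nucleolar GNL3 (1.15 ± 0.11) and NOP56 (0.91 ± 0.12).

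Stretch, natriuretic peptide and fetal cardiac genes rose in 10 and fell in 4 of 23 cases (11 and 4 adjusted over the list alone). The list mean was 0.55 ± 0.28, its median 0.05, and its adjusted p 0.00282, with adjusted p = 0.0687 with an estimated correlation. FHL1, a LIM-domain protein of the sarcomere, rose by 0.69 ± 0.06 (10 of 11 pigs). Among leukocyte adhesion and endothelial activation genes 14 of 26 rose and 2 fell (14 and 3 adjusted over the list alone), including VCAM1 (1.17 ± 0.18), HBEGF (1.34 ± 0.18) and the vasoconstrictor peptide gene EDN1 (0.78 ± 0.11). Its mean was 0.49 ± 0.19 and its adjusted p 0.000195, with adjusted p = 0.177 with an estimated correlation. Glucocorticoid-induced genes rose in 10 and fell in 3 of 19 cases, as many as when adjusted over the list alone, with FKBP5 at 0.58 ± 0.07 and GLUL at 0.53 ± 0.08. The list mean was 0.47 ± 0.18 and the adjusted p 0.000178, with adjusted p = 0.143 with an estimated correlation. Of extracellular matrix and fibrosis genes, 9 of 35 rose and 2 fell (10 and 2 adjusted over the list alone), with a mean of 0.29 ± 0.17, an adjusted p of 0.0209 and adjusted p = 0.670 with an estimated correlation. They included thrombospondin 1, THBS1 (2.08 ± 0.21), and urokinase, PLAU (1.98 ± 0.24). The mean of each of the 10 gene lists that rose was higher in 11 of 11 pigs. In shunt pigs 5 and 6 alone the matrix list did not pass.

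Energy metabolism lists were the 2 that fell by camera. Ventricular cardiomyocyte markers moved with them, by -0.11 ± 0.09 in the shunt pigs (SD, lower in 6 of 6) and -0.05 ± 0.12 in the control pigs (lower in 3 of 5), and passed by fry but not by camera (adjusted p = 0.299, and adjusted p = 0.824 with an estimated correlation). Of oxidative phosphorylation genes, 10 of 42 fell and none rose, as many as when adjusted over the list alone, with a mean of -0.14 ± 0.14 that was lower in 9 of 11 pigs. The adjusted p was 0.000178, and adjusted p = 0.674 with an estimated correlation. The complex I genes NDUFS3 (-0.29 ± 0.07), NDUFA8 (-0.23 ± 0.06) and NDUFB3 (-0.23 ± 0.06) and the ATP synthase gene ATP5D (-0.21 ± 0.05) were among them. No member of the tricarboxylic acid cycle list passed alone, over all probe sets or adjusted over the list alone, and its mean was -0.13 ± 0.17, lower in 9 of 11 pigs (adjusted p = 0.0400, and adjusted p = 0.730 with an estimated correlation). SDHA, the member with the smallest p, stood at -0.18 ± 0.07. In the control pigs alone neither energy list passed, and in shunt pigs 5 and 6 alone the tricarboxylic acid cycle list did not.

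**Figure D3:**
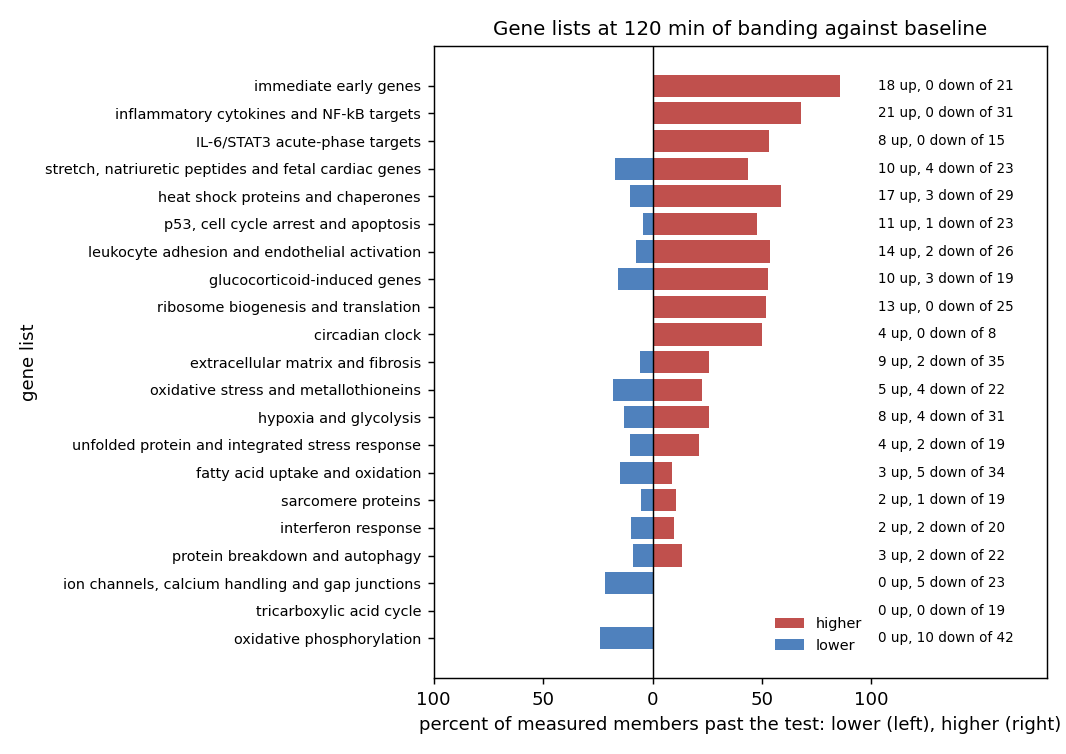
Percent of the measured members of 21 gene lists (vertical axis) that passed the test at 120 min against baseline, drawn to the right where higher and to the left where lower (horizontal axis, percent), with counts beside each bar. The immediate early list had 18 of 21 members higher, and oxidative phosphorylation 10 of 42 lower.

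The other lists did not pass camera at 120 min. Hypoxia and glycolysis genes rose in 8 and fell in 4 of 31 cases (9 and 5 adjusted over the list alone), with a mean of 0.14, a median of -0.04 and an upward test (adjusted p = 0.299). ANGPTL4, an inhibitor of lipoprotein lipase, rose by 2.09 ± 0.23. Of fatty acid uptake and oxidation genes 3 of 34 rose and 5 fell, as many as when adjusted over the list alone. Their mean was 0.10 while their median of -0.09 and the test pointed down (adjusted p = 0.748). The fatty acid transporter SLC27A1 fell by 0.20 ± 0.05. Of ion channel, calcium handling and gap junction genes, 5 of 23 fell and none rose, also when adjusted over the list alone (list adjusted p = 0.738). They were led by the potassium channel KCNJ8 (-0.60 ± 0.05), the calcium pump inhibitor phospholamban, PLN (-0.44 ± 0.09), and the channel subunits KCNIP2 (-0.29 ± 0.08) and KCNE1 (-0.32 ± 0.10). Sarcomere genes had 2 rises and 1 fall among 19 members (2 and 0 adjusted over the list alone), with NRAP at 1.09 ± 0.12, a mean of 0.06, a median of -0.03 and an upward test (adjusted p = 0.738).

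Unfolded protein and integrated stress response genes rose in 4 and fell in 2 of 19 cases, as many as when adjusted over the list alone (adjusted p = 0.297), with ATF4 at 0.51 ± 0.08 and PPP1R15A at 0.78 ± 0.11. Oxidative stress genes rose in 5 and fell in 4 of 22 cases, as many as when adjusted over the list alone (adjusted p = 0.299), and the metallothionein MT1A rose by 1.68 ± 0.33. The interferon list had 2 rises and 2 falls among 20, also when adjusted over the list alone (adjusted p = 0.540), with MX2 at 0.35 ± 0.09 and RSAD2 at -0.44 ± 0.13. Of clock genes 4 of 8 rose and none fell (4 and 2 adjusted over the list alone), including the activator ARNTL (0.46 ± 0.09) and the repressor NFIL3 (0.96 ± 0.20). The clock list had an adjusted p of 0.0604 and passed by fry, in control pigs alone and with the probe sets of a gene averaged. Protein breakdown genes rose in 3 and fell in 2 of 22 cases, as many as when adjusted over the list alone. GABARAPL1 was at 0.52 ± 0.05 and the muscle ubiquitin ligase FBXO32 at -0.49 ± 0.13, and the list mean of -0.01 and median of -0.03 differed in sign from the upward test (adjusted p = 0.738).

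Of the marker lists those of neutrophils and monocytes and of resident macrophages passed camera. Of neutrophil and monocyte markers 3 of 9 rose, as many as when adjusted over the list alone, with a mean of 0.33 ± 0.39 that was higher in 9 of 11 pigs (adjusted p = 0.0257, and adjusted p = 0.607 with an estimated correlation). S100A9, an abundant granulocyte protein, rose by 1.38 ± 0.29 and TYROBP by 0.42 ± 0.13. The mean of this list was 0.72 ± 0.34 in shunt pigs 1 to 4, 0.38 ± 0.15 in shunt pigs 5 and 6 and 0.01 ± 0.10 in the control pigs, where it did not pass. Of resident macrophage markers 2 of 6 rose, also when adjusted over the list alone, with a mean of 0.25 ± 0.28, higher in 9 of 11 pigs (adjusted p = 0.0354, and adjusted p = 0.484 with an estimated correlation), with the haemoglobin scavenger receptor CD163 at 0.74 ± 0.10. That call ended without the pig block and in control pigs alone or shunt pigs 5 and 6 alone.

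The remaining 10 marker lists did not pass camera, and those of red cells, platelets and ventricular cardiomyocytes passed by fry. The lymphocyte list averaged -0.09 ± 0.19 with 1 fall among 7 (CD8A, -0.50 ± 0.11), also adjusted over the list alone. The erythrocyte list averaged -0.40 ± 0.68 with no call among 3, either way, and the platelet list 0.11 ± 0.14 with 1 rise among 3 either way (ITGA2B, 0.20 ± 0.05). Endothelial markers, with a mean of -0.01, had 1 rise (CLDN5, 0.89 ± 0.17) and 2 falls (TEK, -0.41 ± 0.08, and CDH5, -0.18 ± 0.06) among 10, as many as when adjusted over the list alone. Fibroblast markers had 1 rise (COL3A1, 0.44 ± 0.11) and 1 fall (LUM, -0.31 ± 0.10) among 8 (2 and 1 adjusted over the list alone), with a mean of 0.02, a median of -0.09, camera upward and fry downward. Smooth muscle and pericyte markers had 2 rises (CNN1, 1.14 ± 0.12, and TAGLN, 0.61 ± 0.16) and 1 fall among 7, the same adjusted over the list alone, with a mean of 0.16, a median of -0.02, camera upward and fry downward. Adipocyte markers had 1 rise (LEP, 0.22 ± 0.07) and 1 fall (FABP4, -0.33 ± 0.11) among 4, also adjusted over the list alone, with a mean of -0.01, a median of 0.03 and an upward test. Mesothelial markers averaged 0.06 ± 0.17 with no call among 4, either way. Ventricular cardiomyocyte markers averaged -0.08 ± 0.10 with 1 fall among 13 and atrial ones -0.07 ± 1.07 with 1 fall among 4 (NR2F2, -0.52 ± 0.09), both also adjusted over the list alone.

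Of the fixed panel, NPPB, which encodes the natriuretic peptide BNP, rose by 2.16 ± 0.44 (adjusted p = 0.000578), although it was higher in only 8 of 11 pigs. NPPA, for the peptide ANP, stood at 0.04 ± 0.56 (adjusted p = 0.960, 5 of 11 pigs higher) and the myosin gene MYH7 at 0.00 ± 0.03. The strain-responsive ANKRD1 rose by 0.77 ± 0.07 and ATF3, a stress-induced transcription factor, by 3.45 ± 0.41. FOS rose by 1.39 ± 0.43 in 10 of 11 pigs (adjusted p = 0.0160) and EGR1 by 1.39 ± 0.35 in 9. The neutrophil chemokine CXCL8 rose by 1.94 ± 0.35, the protease inhibitor TIMP1 by 2.02 ± 0.26, haem oxygenase HMOX1 2.82-fold, ADM by 0.65 ± 0.11 and PDK4, which restrains glucose oxidation, by 1.41 ± 0.25. VEGFA rose by 0.60 ± 0.08, but of its 4 probe sets 2 were higher and 1 passed in the opposite direction. The haemoglobin gene HBB (-0.22 ± 0.10, 2 of 11 pigs higher) did not pass, and it did at -0.27 without control pig 4.

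Within the array sets PTX3 rose by 4.51 ± 1.66 in shunt pigs 1 to 4, 4.57 ± 0.95 in shunt pigs 5 and 6 and 4.02 ± 1.11 in the control pigs (SD). HSPA6 rose by 5.44 ± 1.74, 5.45 ± 1.11 and 2.32 ± 1.60 in the same order, and NPPB by 2.25 ± 2.75, 3.28 ± 0.03 and 1.64 ± 2.01. The changes of CIRBP were -1.44 ± 0.27, -1.25 ± 0.14 and -0.77 ± 0.44. The cytokine list averaged 1.18 ± 0.54, 0.97 ± 0.07 and 0.76 ± 0.33, and the heat shock list 0.75 ± 0.35, 0.65 ± 0.16 and 0.35 ± 0.19.

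The further 60 min of banding in the 5 control pigs left no gene past the threshold. The smallest p-values belonged to CEP295 (0.24 ± 0.07), ADAM28 (0.27 ± 0.08), the mitotic cyclin CCNB1 (0.50 ± 0.16), the leukocyte integrin ITGAM (0.23 ± 0.08) and PKIB (0.59 ± 0.20) among higher values. Among lower values they belonged to DGKA (-0.38 ± 0.11), PANK1, an enzyme of coenzyme A synthesis (-0.41 ± 0.13), NOSTRIN (-0.27 ± 0.09), RITA1 (-0.24 ± 0.08) and GLRB (-0.24 ± 0.09). None of these passed. NPPB stood at 1.02 ± 0.65, also without passing. The neutrophil and monocyte markers averaged 0.25 ± 0.17 (SD, higher in 5 of 5 pigs) and were the only list of 33 to pass camera. Their adjusted p was 0.0450, and adjusted p = 0.935 with an estimated correlation, and the call ended with the probe sets of a gene averaged. With the arrays centred on their medians oxidative phosphorylation genes (higher) and interferon and glucocorticoid-induced genes (lower) passed too, the last of these also without the pig block. No member of the neutrophil and monocyte list passed over all probe sets and 2 of 9 did adjusted over the list alone. In limma 0 probe sets passed, 737 had an unadjusted p under 0.05, and every alternative fit run also gave 0.

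In the 6 shunt pigs, 60 min with the shunt also left 0 probe sets past the threshold in limma, with 2146 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0732. The smallest p-values among lower genes belonged to PANK1 (-0.63 ± 0.12), ZNF397 (-0.51 ± 0.11), the peptidase DPP4 (-0.39 ± 0.09), FAM216B (-0.68 ± 0.16) and XPO7 (-0.28 ± 0.07). Among higher genes they belonged to PIGX (0.31 ± 0.06), POGK (0.38 ± 0.08), FCF1, which acts in ribosome assembly (0.36 ± 0.08), the nucleolar MYBBP1A (0.29 ± 0.07) and MBD2 (0.33 ± 0.08). None of the 10 passed. PANK1 passed without shunt pig 5 (-0.69), where 11 probe sets did, and ZNF397 without shunt pig 4 (-0.63), where 3 did. With pig as a random block 1 probe set passed, and with array quality weights 46 did.

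By camera 4 lists moved in the shunt pigs over these 60 min, none of which passed with an estimated correlation or by fry. With the arrays centred on their medians fatty acid uptake and oxidation genes (lower) passed camera too (adjusted p = 0.0443). Ribosome biogenesis genes averaged 0.21 ± 0.29 (SD, higher in 4 of 6 pigs, adjusted p = 1.72e-08, and adjusted p = 0.786 with an estimated correlation) and neutrophil and monocyte markers 0.29 ± 0.53 (5 of 6, adjusted p = 0.0197, and adjusted p = 0.786 with an estimated correlation). Oxidative phosphorylation genes averaged -0.06 ± 0.11 (adjusted p = 0.0224, and adjusted p = 0.786 with an estimated correlation) and tricarboxylic acid cycle genes -0.10 ± 0.12 (adjusted p = 0.00566, and adjusted p = 0.786 with an estimated correlation), both lower in 5 of 6 pigs. No member of these lists passed. S100A9 stood at 1.07 ± 0.39 and NPPB at 0.95 ± 0.60. S100A9 was not higher in the shunt pigs alone: in the control pigs it went from 4.78 ± 0.32 at 120 min to 6.03 ± 0.61 at the last biopsy (SD), also without passing.

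The effect of the shunt itself was tested as the change after 120 min in the shunt arm minus that in the control arm. No gene passed. The largest positive values of low p were those of CYP3A29, a cytochrome P450 (0.71 ± 0.20), the cadherin CDH6 (0.40 ± 0.12), POGK (0.38 ± 0.12), FARSA (0.34 ± 0.11) and NME3 (0.32 ± 0.10). The negative ones were the signalling adaptor TRAF6 (-0.68 ± 0.20), the chemokine CCL8 (-0.74 ± 0.24), SNAP91 (-0.45 ± 0.15), ELOVL3 (-0.42 ± 0.13) and C7H14orf1 (-0.28 ± 0.09). None passed. In limma 0 probe sets passed, 737 had an unadjusted p under 0.05, fewer than the 1200 expected with no change, and all alternative fits run gave 0. The later change of NPPB was 0.95 in the shunt arm and 1.02 in the control arm.

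By camera 4 lists differed for the shunt effect, and none with an estimated correlation or by fry. Oxidative phosphorylation genes averaged -0.06 in the shunt arm, lower in 5 of 6 pigs, and 0.04 in the control arm, lower in 2 of 5 (difference -0.10, adjusted p = 0.000121, and adjusted p = 0.779 with an estimated correlation). Tricarboxylic acid cycle genes, lower in 5 of 6 and 2 of 5 pigs, differed by -0.12 (adjusted p = 0.00175, and adjusted p = 0.779 with an estimated correlation) and ion channel genes, with the same numbers of pigs, by -0.12 (adjusted p = 0.0432, and adjusted p = 0.779 with an estimated correlation). Ribosome biogenesis genes averaged 0.21 and 0.04, higher in 4 of 6 and 3 of 5 pigs (difference 0.17, adjusted p = 0.000121, and adjusted p = 0.779 with an estimated correlation). Ventricular cardiomyocyte markers, 11 of whose 13 genes stand in other lists, moved with the energy genes, by -0.06 ± 0.08 (SD, lower in 5 of 6 pigs) and 0.02 ± 0.13 (lower in 2 of 5), and their difference of -0.08 did not pass (adjusted p = 0.0963, and adjusted p = 0.779 with an estimated correlation). The ion channel call ended without the pig block and with the probe sets of a gene averaged.

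Over the whole course, from baseline to the last biopsy, PTX3 was 22.8-fold higher in the control pigs (4.51 ± 0.50, n = 5, adjusted p = 8.38e-06), CCL2 9.01-fold (3.17 ± 0.43) and CYR61 8.45-fold (3.08 ± 0.40). ATF3 (2.85 ± 0.61), BTG2 (2.75 ± 0.43), MT-2B (2.72 ± 0.44), NPPB (2.67 ± 0.65, adjusted p = 0.0110), IL6 (2.57 ± 0.64, adjusted p = 0.0123), GADD45A (2.28 ± 0.31) and IER3 (2.22 ± 0.32) were the other named rises. The named falls were MAP10 (-1.23 ± 0.13), TNFSF10, the death ligand TRAIL (-1.21 ± 0.25), STOX1 (-1.18 ± 0.17), CIRBP (-1.13 ± 0.15), PHACTR3 (-1.12 ± 0.20), CEP85 (-1.10 ± 0.23), FAM198B (-1.10 ± 0.17), FPGT (-1.07 ± 0.17), ZUFSP (-1.02 ± 0.16) and SEPT8 (-0.99 ± 0.08). All 20 moved the same way in 5 of 5 pigs. Of the panel ANKRD1 (0.57 ± 0.11), ADM (0.84 ± 0.17), VEGFA (0.52 ± 0.12), HMOX1 (1.32 ± 0.35), TIMP1 (1.55 ± 0.39) and EGR1 (1.94 ± 0.52, 4 of 5 pigs) rose, while FOS (1.60 ± 0.63), CXCL8 (1.56 ± 0.52), PDK4 (0.44 ± 0.37), NPPA, HBB and MYH7 did not pass.

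In limma 2110 probe sets passed in the control arm, 840 higher and 1270 lower, covering 675 genes. Without control pig 2 the count was 849 and without control pig 1 it was 1314. Without control pig 2 NPPB (2.49), IL6 (1.86), EGR1 (1.66), HMOX1 (1.16) and TIMP1 (1.24) no longer passed. The same held for NPPB (2.35) and EGR1 (1.76) without control pig 3, EGR1 (1.59) without control pig 4 and HMOX1 (1.17) without control pig 1. Without the pig block 826 passed, and NPPB, IL6, TNFSF10, HMOX1, VEGFA and TIMP1 did not.

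Of 33 lists 13 passed camera in the control arm, all higher, with only the p53 list passing with an estimated correlation and 11 by fry. The means of 11 lists were higher in 5 of 5 pigs and those of the matrix and resident macrophage lists in 4 of 5. Immediate early genes rose in 13 of 21 cases (15 adjusted over the list alone), with a mean of 1.31 ± 0.38 (SD, adjusted p = 3.71e-14, and adjusted p = 0.111 with an estimated correlation). The cytokine list had 7 rises among 31 (9 adjusted over the list alone, mean 0.78 ± 0.39, adjusted p = 3.92e-08, and adjusted p = 0.178 with an estimated correlation) and the IL-6/STAT3 list 7 among 15 (8 adjusted over the list alone, mean 0.55 ± 0.19, adjusted p = 4.58e-06, and adjusted p = 0.107 with an estimated correlation). In the p53 list 9 of 23 rose and 1 fell (12 and 1 adjusted over the list alone, mean 0.45 ± 0.13, adjusted p = 4.23e-06, and adjusted p = 0.0248 with an estimated correlation), with TNFRSF12A at 1.54 ± 0.21. Of glucocorticoid-induced genes 8 of 19 rose (8 and 1 fall adjusted over the list alone, mean 0.42 ± 0.17, adjusted p = 9.39e-05, and adjusted p = 0.107 with an estimated correlation), with FKBP5 at 0.82 ± 0.11. Ribosome biogenesis genes rose in 6 of 25 cases (8 adjusted over the list alone, mean 0.30 ± 0.16, adjusted p = 4.23e-06, and adjusted p = 0.286 with an estimated correlation), with EIF4A1 at 1.13 ± 0.17. Heat shock genes rose in 5 of 29 cases, also adjusted over the list alone (mean 0.34 ± 0.23, adjusted p = 0.000352, and adjusted p = 0.494 with an estimated correlation). The stretch list had 7 rises and 1 fall among 23 (7 and 2 adjusted over the list alone, mean 0.44 ± 0.16, adjusted p = 0.00586, and adjusted p = 0.101 with an estimated correlation). Hypoxia genes, with the glucose transporter SLC2A1 at 0.41 ± 0.10, had 7 rises and 2 falls among 31 (9 and 2 adjusted over the list alone, mean 0.18 ± 0.06, adjusted p = 0.0116, and adjusted p = 0.178 with an estimated correlation). No oxidative phosphorylation or tricarboxylic acid cycle gene passed, over all probe sets or adjusted over the list alone, and their means were -0.04 ± 0.08 and -0.08 ± 0.10.

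In the shunt pigs PTX3 was 34.5-fold higher at the last biopsy than at baseline (5.11 ± 0.45, n = 6, adjusted p = 2.46e-08) and HSPA6 26.6-fold (4.73 ± 0.74, adjusted p = 2.72e-05). The calcium-binding granulocyte protein gene S100A9 was 11.2-fold higher (3.48 ± 0.39, adjusted p = 4.94e-07) and NPPB 11.6-fold (3.54 ± 0.60, adjusted p = 6.11e-05). AREG (3.71 ± 0.44), IL6 (3.63 ± 0.58), CCL2 (3.50 ± 0.39), MT-2B (3.28 ± 0.40), LMCD1, a LIM-domain regulator of transcription (3.20 ± 0.35), and CYR61 (3.09 ± 0.36) were the other named rises. STOX1, a winged-helix transcription factor, was 5.38-fold lower (-2.43 ± 0.16, adjusted p = 3.59e-10). The other falls were CEP85 (-2.15 ± 0.21), FPGT (-1.82 ± 0.16), FAM198B (-1.74 ± 0.16), the GABA receptor subunit GABRA4 (-1.58 ± 0.20), the retinaldehyde dehydrogenase ALDH1A1 (-1.52 ± 0.18), NAP1L3 (-1.51 ± 0.16), FAIM (-1.47 ± 0.17), PPTC7, a mitochondrial phosphatase (-1.46 ± 0.18), and METTL18 (-1.45 ± 0.11). All 20 moved the same way in 6 of 6 pigs.

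Of the panel ANKRD1 (1.03 ± 0.10), ATF3 (2.72 ± 0.55), CXCL8 (3.09 ± 0.47), HMOX1 (2.09 ± 0.32), PDK4 (1.70 ± 0.33) and TIMP1 (2.86 ± 0.36) rose in the shunt arm. FOS (1.02 ± 0.58), EGR1 (0.49 ± 0.47), NPPA, HBB and MYH7 did not pass. VEGFA rose by 0.48 ± 0.11, with 1 of its probe sets in the opposite direction, and the mean of its probe sets (0.12) did not pass. ADM (0.47 ± 0.15) passed, but not without shunt pig 1 (0.41), shunt pig 2 (0.35) or shunt pig 3 (0.41), nor without the pig block. In limma 7815 probe sets passed, 3200 higher and 4615 lower, covering 2725 genes. Shunt pigs 1 to 4 alone gave 4804 and shunt pigs 5 and 6 alone 1172.

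Of 33 lists 12 passed camera in the shunt arm, 10 higher and 2 lower, with none passing with an estimated correlation and 19 by fry. The means of the 10 were higher in 6 of 6 pigs, except those of the immediate early and leukocyte adhesion lists, which were higher in 5. Ribosome biogenesis genes rose in 18 of 25 cases, as many as when adjusted over the list alone, with a mean of 0.66 ± 0.29 (SD, adjusted p = 6.95e-09, and adjusted p = 0.264 with an estimated correlation). EIF4A1 stood at 1.85 ± 0.15, GNL3 at 1.72 ± 0.14 and the RNA polymerase subunit POLR1C at 1.17 ± 0.13. Cytokine genes rose in 19 of 31 cases (21 adjusted over the list alone, mean 1.24 ± 0.68, adjusted p = 6.95e-09, and adjusted p = 0.264 with an estimated correlation), with the receptor IL1R1 4.60-fold higher. Heat shock genes rose in 18 and fell in 1 of 29 cases (19 and 3 adjusted over the list alone, mean 0.76 ± 0.56, adjusted p = 1e-05, and adjusted p = 0.470 with an estimated correlation), with HSPB8 at 1.65 ± 0.20. The IL-6/STAT3 list had 9 rises among 15 (10 adjusted over the list alone, mean 0.86 ± 0.40, adjusted p = 1.94e-05, and adjusted p = 0.197 with an estimated correlation). The immediate early list had 13 among 21, also adjusted over the list alone (mean 1.15 ± 0.91, adjusted p = 9.7e-06, and adjusted p = 0.470 with an estimated correlation).

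Of oxidative phosphorylation genes 28 of 42 fell in the shunt arm and none rose (33 falls adjusted over the list alone), with a mean of -0.24 ± 0.21 that was lower in 5 of 6 pigs. The list had an adjusted p of 3.46e-06, and adjusted p = 0.616 with an estimated correlation. ATP5D (-0.41 ± 0.07), NDUFB10 (-0.38 ± 0.08) and NDUFS3 (-0.44 ± 0.10) were among them. In the tricarboxylic acid cycle list 12 of 19 fell (14 adjusted over the list alone, mean -0.25 ± 0.18, lower in 5 of 6 pigs, adjusted p = 0.00186, and adjusted p = 0.616 with an estimated correlation), with citrate synthase CS at -0.33 ± 0.08 and SDHA at -0.35 ± 0.09. Ventricular cardiomyocyte markers moved with them (-0.17 ± 0.12, lower in 5 of 6 pigs) and passed by fry and without the pig block, but not by camera (adjusted p = 0.0639, and adjusted p = 0.648 with an estimated correlation). Neutrophil and monocyte markers rose in 7 of 9 cases, as many as when adjusted over the list alone, with a mean of 0.89 ± 0.52 that was higher in 6 of 6 pigs (adjusted p = 0.000438, and adjusted p = 0.394 with an estimated correlation). S100A8 (0.99 ± 0.20), LCP1 (0.94 ± 0.19) and TYROBP (0.89 ± 0.17) were among them. Leukocyte adhesion genes had 13 rises and 3 falls among 26 (14 and 3 adjusted over the list alone, mean 0.67 ± 0.44, adjusted p = 0.000558, and adjusted p = 0.264 with an estimated correlation), with E-selectin, SELE, at 3.05 ± 0.46. The p53 list had 11 rises and 2 falls among 23, also adjusted over the list alone (mean 0.56 ± 0.24, adjusted p = 0.00150, and adjusted p = 0.197 with an estimated correlation). Matrix genes, with tenascin TNC at 2.50 ± 0.39, had 12 rises and 3 falls among 35 (12 and 4 adjusted over the list alone, mean 0.43 ± 0.36, adjusted p = 0.0125, and adjusted p = 0.616 with an estimated correlation). The stretch list had 10 rises and 4 falls among 23 (11 and 4 adjusted over the list alone, adjusted p = 0.0196, and adjusted p = 0.197 with an estimated correlation), with FHL1 at 1.19 ± 0.08 and FHL2 at -1.05 ± 0.11.

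**Figure D4:**
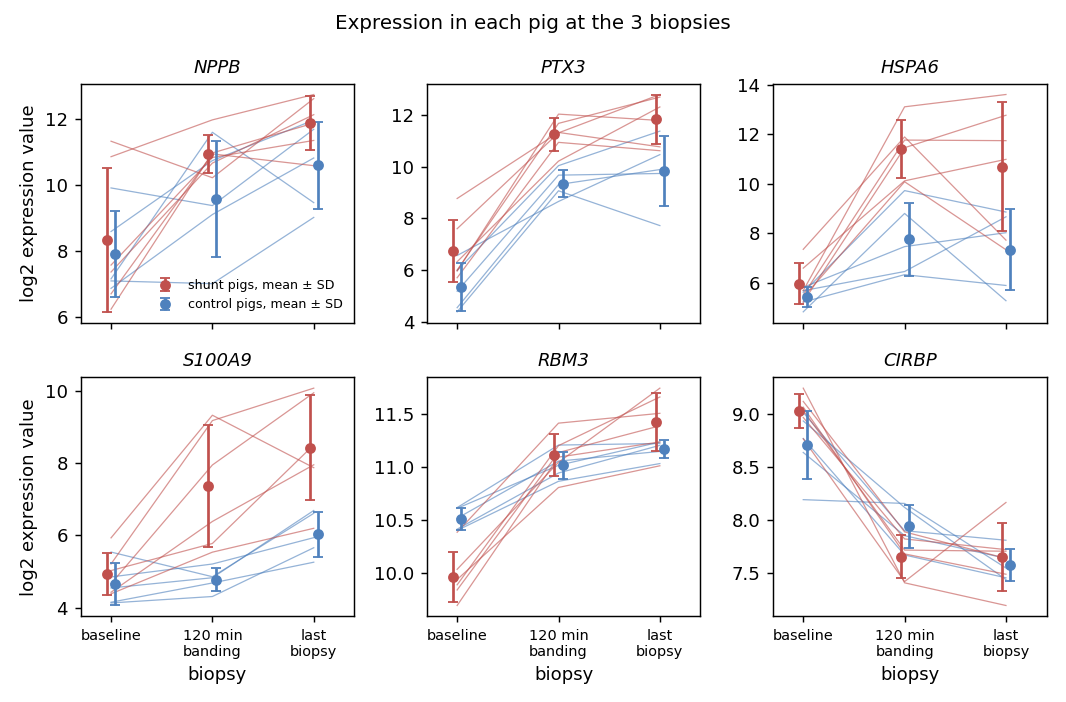
Log2 expression value (vertical axes) of NPPB, PTX3, HSPA6, S100A9, RBM3 and CIRBP at the 3 biopsies (horizontal axes), with a thin line per pig and points with bars for the mean and SD of 6 shunt and 5 control pigs. S100A9 averaged 8.42 at the last biopsy of the shunt pigs and 6.03 in the control pigs, and RBM3 began at 9.97 in the shunt pigs and 10.51 in the control pigs.

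The whole course was also compared between the arms, as the change from baseline to the last biopsy in the shunt arm minus that in the control arm. In limma 1 probe set passed and 2922 had an unadjusted p under 0.05. It was that of RBM3, a cold-inducible RNA-binding protein, whose rise was larger by 0.80 ± 0.12 in the shunt arm (adjusted p = 0.01995). RBM3 went from 9.97 ± 0.23 to 11.42 ± 0.27 in the shunt pigs and from 10.51 ± 0.10 to 11.17 ± 0.08 in the control pigs (SD), so that the levels of the arms lay further apart at baseline than at the end. Its rise was 1.52 ± 0.31 in shunt pigs 1 to 4 and 1.33 ± 0.30 in shunt pigs 5 and 6. The genes next in line, none of which passed with all pigs and probe sets, were FHL1 (0.64 ± 0.12), POGK (0.60 ± 0.12), FSTL3, an inhibitor of activins (0.64 ± 0.13), and LRRN3 (0.99 ± 0.21) among positive differences. Negative ones were STOX1 (-1.25 ± 0.23), STC1, a secreted stanniocalcin (-1.27 ± 0.26), ANKRD37 (-1.04 ± 0.22), CXXC5 (-0.65 ± 0.14) and SLC2A1 (-0.61 ± 0.13). FHL1 and STOX1 came to pass with the probe sets of a gene averaged and without shunt pig 4, shunt pig 5 or control pig 3. Without shunt pig 4 or 5 FSTL3, LRRN3, ANKRD37 and CXXC5 passed, and POGK, STC1 and SLC2A1 without shunt pig 4. The differences for S100A9 (2.10 ± 0.58) and NPPB (0.87 ± 0.88) did not pass either.

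The call of RBM3 ended without shunt pig 1 (0.74), 2 (0.75), 3 (0.78) or 6 (0.78), without control pig 1, 4 or 5 (0.79 each), and without the pig block. Without shunt pig 4 the count was 274, without shunt pig 5 it was 118, without control pig 2 it was 4 and without control pig 3 it was 5, while leaving out any of the other 7 pigs gave 0. With array quality weights 189 passed. By camera 10 lists differed, none of them with an estimated correlation or by fry. Ribosome biogenesis genes differed by 0.37 between the arms (adjusted p = 3.32e-08, and adjusted p = 0.538 with an estimated correlation), cytokine genes by 0.46 (adjusted p = 0.000332, and adjusted p = 0.538 with an estimated correlation), heat shock genes by 0.42 (adjusted p = 0.000223, and adjusted p = 0.538 with an estimated correlation) and IL-6/STAT3 targets by 0.30 (adjusted p = 0.0340, and adjusted p = 0.538 with an estimated correlation), and each of these means was higher than at baseline in 6 of 6 shunt and 5 of 5 control pigs. The same pig counts held for neutrophil and monocyte markers, which differed by 0.64 (adjusted p = 0.000332, and adjusted p = 0.538 with an estimated correlation). Red cell markers differed by 1.09 (adjusted p = 0.0178, and adjusted p = 0.538 with an estimated correlation), with a mean change of 0.40 ± 0.53 in the shunt arm (5 of 6 pigs higher) and -0.70 ± 0.60 in the control arm (5 of 5 lower). Oxidative phosphorylation genes differed by -0.20 (adjusted p = 3.12e-10, and adjusted p = 0.538 with an estimated correlation) and tricarboxylic acid cycle genes by -0.17 (adjusted p = 0.000763, and adjusted p = 0.538 with an estimated correlation), both lower in 5 of 6 shunt and 4 of 5 control pigs. Ventricular cardiomyocyte markers differed by -0.14 (adjusted p = 0.00560, and adjusted p = 0.538 with an estimated correlation) and sarcomere genes by -0.06 (adjusted p = 0.0409, and adjusted p = 0.538 with an estimated correlation). Adjusted over the list alone, 14 ribosome biogenesis genes, 5 neutrophil and monocyte markers and 2 red cell markers passed. The sarcomere call ended with the arrays centred on their medians.

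Both arms had been treated alike up to 120 min, so the difference between their responses by then was examined as a check on the arms before the shunt. No gene passed. RBM3 (0.64 ± 0.12) and FHL1 (0.61 ± 0.12) came nearest, with an adjusted p of 0.203 each, followed by PDE8A (0.68 ± 0.17), the endotoxin receptor TLR4 (0.75 ± 0.19) and S100A9 (2.28 ± 0.58). HSPA6 stood at 3.12 ± 1.10. Negative differences were those of STC1 (-1.27 ± 0.26), STOX1 (-1.04 ± 0.23), ANKRD37 (-0.92 ± 0.22), BANP (-0.66 ± 0.16) and SLC2A1 (-0.50 ± 0.13). None of these passed. In limma 0 probe sets passed, 1655 had an unadjusted p under 0.05, and every alternative fit run gave 0.

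By camera 6 lists differed at 120 min, none with an estimated correlation or by fry. Neutrophil and monocyte markers averaged 0.61 ± 0.32 in the shunt arm and 0.01 ± 0.10 in the control arm (SD, difference 0.60, adjusted p = 4.36e-05, and adjusted p = 0.571 with an estimated correlation). The heat shock list averaged 0.72 ± 0.29 and 0.35 ± 0.19 (0.37, adjusted p = 0.000893, and adjusted p = 0.695 with an estimated correlation) and the cytokine list 1.11 ± 0.43 and 0.76 ± 0.33 (0.34, adjusted p = 0.000680, and adjusted p = 0.695 with an estimated correlation). Ribosome biogenesis genes averaged 0.45 ± 0.06 and 0.25 ± 0.08 (0.20, adjusted p = 0.000680, and adjusted p = 0.695 with an estimated correlation) and oxidative phosphorylation genes -0.19 ± 0.15 and -0.08 ± 0.12 (-0.11, adjusted p = 4.36e-05, and adjusted p = 0.794 with an estimated correlation). Beside these, ventricular cardiomyocyte markers averaged -0.11 ± 0.09 and -0.05 ± 0.12 (-0.06, adjusted p = 0.143, and adjusted p = 0.794 with an estimated correlation). Red cell markers, which did not pass either, averaged -0.06 ± 0.32 and -0.81 ± 0.80 (0.75, adjusted p = 0.0569, and adjusted p = 0.571 with an estimated correlation). Their difference between the arms was thus larger than that of the neutrophil and monocyte markers. The stretch list differed by 0.28 (adjusted p = 0.0441, and adjusted p = 0.571 with an estimated correlation), and its call ended without the pig block and with the probe sets of a gene averaged.

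At baseline the arms differed in 5 probe sets in limma, 2 higher and 3 lower in the shunt arm, with 2820 at an unadjusted p under 0.05. RETSAT, a retinol saturase, was lower by -1.16 ± 0.14 (adjusted p = 0.0389), the unconventional myosin MYO5B by -2.39 ± 0.34 (adjusted p = 0.0450), and the glucose transporter SLC2A1 was higher by 0.76 ± 0.11 (adjusted p = 0.0450). The other calls, chosen for naming after their values were seen, were a pair of probe sets with no symbol (0.56 ± 0.08 and -0.49 ± 0.07). Not passing were PSMD5, TALDO1, DKK1 and PSMD10 among higher values and CPT1A (-0.85 ± 0.15), which brings fatty acids into mitochondria, the lipase LIPE (-1.13 ± 0.20) and NAAA (-0.67 ± 0.11) among lower ones. Without control pig 3 the calls of RETSAT and MYO5B remained (2 calls) while SLC2A1 (0.73) did not pass, without shunt pig 6 there was 1 call, and without any of the other 9 pigs there were 0. With the array set as a random block 0 passed.

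Across the 6765 genes, which are not independent replicates, the response at 120 min of the control pigs correlated with that of the shunt pigs, which shared no array, with Pearson's r of 0.85 and Spearman's rho of 0.74. The direction was the same for 77.1% of genes, and the slope of the shunt response on the control response was 1.18. Between array sets r was 0.813, 0.869 and 0.849. The changes after 120 min correlated between the arms with r of 0.29 and rho of 0.22. For the whole course r was 0.84, rho 0.75 and the slope 1.31. Of 840 probe sets higher in the control arm over the whole course, 739 (88.0%) were also higher in the shunt arm, where independence would give 112, and 1156 of 1270 lower ones (91.0%) were also lower, where it would give 244. A single probe set was called in opposite directions.

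The change after 120 min was compared with the response before it. Between different pigs r was 0.19 for the control response against the later change of the shunt pigs and 0.13 for the shunt response against the later change of the control pigs. Within an arm both changes use the arrays of 120 min, which by itself drives r to about -0.50 (simulated covariance -0.00830 in the control and -0.00686 in the shunt arm). The measured r was -0.10 in the control pigs (covariance -0.00294) and 0.31 in the shunt pigs (covariance 0.0167).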

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

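The tests of response size over pigs and array sets, those that set marker lists against each other and those of RBM3 and CIRBP were chosen only after the result was seen, while the count without 1 pig and the comparisons between arms were planned.

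In 13 of 281 groups of pigs (4.63%) a single pig stood far from the others by Dixon's test, which chance would give in about 1 of 20. At 120 min PTX3 had risen by 2.09 in control pig 5 against 4.06 to 4.77 in the other control pigs, and TLR4 by 0.62 in control pig 4 against 0.19 to 0.31. CIRBP stood at -1.84 in shunt pig 1 (others -1.39 to -1.15), FAIM at -2.20 in shunt pig 4 (-1.24 to -0.84) and SEPT8 at -0.48 in control pig 3 (-0.93 to -0.82). At the last biopsy MT-2B was up by 0.64 in control pig 3 (2.87 to 3.71) and RBM3 by 0.79 in control pig 2 (0.60 to 0.63), and FAIM stood at -0.41 in shunt pig 5 (-1.78 to -1.64). The baseline level of PSMD10 was 7.59 in shunt pig 2 (7.76 to 7.84). Of list means at 120 min, the hypoxia list was high in shunt pig 2 (0.28 against 0.03 to 0.12). Shunt pig 1 was high in the matrix list (0.70 against 0.22 to 0.35), in resident macrophage markers (0.80 against 0.09 to 0.29) and in smooth muscle and pericyte markers (0.66 against 0.09 to 0.25).

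Several lists differed between the arms by camera at the preset correlation, and none with an estimated one. After 120 min the difference, shunt minus control, was -0.10 for oxidative phosphorylation, -0.12 for the tricarboxylic acid cycle, -0.12 for ion channels and 0.17 for ribosome biogenesis. Over the whole course it was 0.46 for cytokines, 0.30 for IL-6/STAT3 targets, 0.42 for heat shock, 0.37 for ribosome biogenesis, 0.64 for neutrophil and monocyte markers and 1.09 for red cell markers, and -0.20, -0.17, -0.0636 and -0.14 for oxidative phosphorylation, the tricarboxylic acid cycle, sarcomere proteins and ventricular cardiomyocyte markers. By 120 min it was 0.34 for cytokines, 0.37 for heat shock, 0.28 for stretch genes, 0.20 for ribosome biogenesis, 0.60 for neutrophil and monocyte markers and -0.11 for oxidative phosphorylation. RBM3 was the only gene whose change differed between the arms, by 0.80 over the whole course, and its call ended without any of 7 of the pigs. Outside the biological measurement, the Dap control RNA gave a log2 signal of 7.72 in the control pigs and 8.53 in shunt pigs 5 and 6, against 3.20 in shunt pigs 1 to 4.

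The response by 120 min was larger in the shunt pigs, although no shunt had yet been placed: the slope of the change in each pig on the mean change of the other pigs was 1.10 ± 0.22 (SD, n = 6) against 0.72 ± 0.20 (n = 5), a difference of 0.377 with an exact two-sided permutation p of 0.0216 over 462 splits (smallest possible 0.00216). The difference of 0.468 at the last biopsy (1.15 ± 0.41 against 0.68 ± 0.22) had an exact p of 0.0519, and 11 of 100 splits gave as many as the real 1655 probe sets at an unadjusted p under 0.05 at 120 min, so a chance assignment of pigs to the arms stays open. The extra pig of the shunt arm is not behind its larger number of whole-course calls, since leaving out 1 shunt pig still gave at least 6497 against 2110 in the control arm. Shunt pigs 1 to 4 differed from shunt pigs 5 and 6 by 0.0789 (exact two-sided permutation p = 0.733 over 15 splits, smallest possible 0.0667), but no array set held both arms, so the array set and the arm cannot be told apart. A difference in the animals themselves, such as in the severity of the failure before the shunt, stays open and untested.

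Neutrophil and monocyte markers were higher at the last biopsy than at baseline in the shunt pigs (0.89 ± 0.52, n = 6, none of the 9 genes in another list), and S100A9 went from 4.94 ± 0.58 to 8.42 ± 1.45 in biopsies that were not sorted. Lymphocyte markers averaged -0.03 ± 0.18, and the difference of 0.92 ± 0.59 was positive in 6 of 6 pigs (exact two-sided sign-flip p = 0.03125, the smallest possible), which argues against more white cells of every kind. Red cell markers averaged 0.40 ± 0.53, but the difference of 0.50 ± 0.41, positive in 5 of 6 pigs, had an exact sign-flip p of 0.0938, so more blood in the last biopsies stays open. By 120 min the neutrophil and monocyte markers had risen by 0.61 ± 0.32 against -0.06 ± 0.32 for red cell markers (positive difference in 6 of 6 pigs, exact sign-flip p = 0.03125, the smallest possible). That part of the rise came without a rise of the 3 red cell genes, but the list was picked likewise. Red cell genes do not show how many neutrophils the blood held, so blood stays open there too. In the control pigs the same lists, in that order, averaged 0.01 ± 0.10 and -0.81 ± 0.80 by 120 min. At the last biopsy they averaged 0.25 ± 0.17 and -0.70 ± 0.60. The neutrophil and monocyte markers thus stood above the red cell markers in both arms, a gap not tested in the control pigs. A hypothesis that neutrophils or monocytes had entered the muscle, or were held in its vessels, may be followed up, and induction of these genes in resident cells was not tested.

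RBM3 rose by 0.85 ± 0.06 by 120 min in 11 of 11 pigs while CIRBP fell by 1.10 ± 0.10 in 11 of 11, although mild cooling is known to induce both. The upper 95% bound of the CIRBP change was -0.89 and the lower bound of the RBM3 change 0.73, which restate these opposite changes and are no separate test of temperature. They leave no room for cooling alone or warming alone to have moved both in the known direction, while temperature as the cause of either change stays open. Temperatures are not in the labels, both transcripts had 1 probe set each, and no biological explanation was tested.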

How the results depend on the processing

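The alternatives by array set were chosen only after the data were seen, and the others were planned. No result was reversed, which for a list means passing in opposite directions before and after. The counts of 0 for the later change in the control arm, for the shunt effect and for the arms' responses at 120 min stayed at 0 in every fit run, leave-one-out fits included. Single genes were refitted only with averaged probe sets, centred arrays, no pig block and each pig left out. In these fits the 35 named or panel genes called at 120 min passed in all 490 alternative values. The genes named as the largest changes had been required to pass with the same direction in every pig, which favours that result. Of the counts of probe sets or genes 131 values stayed within 1.5 times, 13 were higher and 45 lower. For single genes 2578 values kept their side of the threshold, 22 came to pass, 61 ceased to and 88 changed sign without passing before or after. For lists the numbers were 1244, 24, 105 and 46, but here the 46 include any change of sign in a list that did not pass both before and after. The response at 120 min (6964 probe sets) gave 1118 with a minimum of 1.5-fold, 2426 with 1 probe set per gene and 2285 with the probe sets of a gene averaged, all of which restrict what is counted. With fewer pigs it gave 2369 (shunt pigs 1 to 4), 1790 (control pigs) and 454 (shunt pigs 5 and 6), and 5825 to 7348 leaving out 1 pig. For the later change in the shunt arm (0) pig as a random block gave 1, array quality weights 46, and leaving out 1 pig 0 to 11. The whole course in the control arm (2110) gave 826 without the pig block, 3440 with weights, 733 at 1.5-fold, 730 with 1 probe set per gene, 621 with averaged probe sets, and 849 to 1635 leaving out 1 pig. In the shunt arm (7815) it gave 2422 at 1.5-fold, 2881 and 2779 by gene, 4804 and 1172 in shunt pigs 1 to 4 and 5 to 6, and 6497 to 8047 leaving out 1 pig. The difference between the arms over the whole course (1) gave 0 without the pig block, 0 on the arrays compared alone, 0 with shunt pigs 1 to 4 only, 189 with weights, 3 and 3 by gene, and 0 to 274 leaving out 1 pig. The baseline difference (5) gave 1 on centred arrays, 1 with an intensity trend and robust eBayes, 3 at 1.5-fold, 3 and 3 by gene, 0 with shunt pigs 1 to 4, 16 with shunt pigs 5 and 6, 0 with the array set as a random block, and 0 to 2 leaving out 1 pig. The 14 lists at 120 min became 1 with an estimated correlation. The estimate was above the preset 0.01 in each list, from 0.012 (stretch) to 0.60 (oxidative phosphorylation), with 0.51 for immediate early genes. The preset thus treats genes that varied together as nearly independent, and the small adjusted p-values of camera rest on it. Apart from this and from fits with fewer pigs or features, the cause of a change was not tested. Array weights ran from 0.306 to 4.06, and the estimated correlation was 0.248 within pigs and 0.0135 within array sets at baseline. Lists were not tested again with each pig left out. Arrays give no depth, and signal near background limits the dimmest probe sets, whose removal (30%) left every count within 1.5 times.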

Other observations

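The tests of a return toward baseline were chosen only after the result was seen, while the splits of the pigs were planned.

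At the last biopsy of the shunt pigs 5 of 34 fatty acid genes were higher than at baseline and 11 lower, also adjusted over the list alone, and the mean (0.05) differed in sign from the median (-0.15) and the test (adjusted p = 0.486). Of ion channel and calcium handling genes 2 of 23 rose and 7 fell, also adjusted over the list alone, with KCNJ8 at -0.84 ± 0.07 (SE, n = 6), PLN at -0.77 ± 0.13, KCNIP2 at -0.45 ± 0.10 and the kinase CAMK2D at -0.25 ± 0.06 (list adjusted p = 0.430). Sarcomere genes rose in 2 and fell in 5 of 19 cases (2 and 6 adjusted over the list alone), with troponin T, TNNT2, at -0.21 ± 0.06, a mean of 0.00, a median of -0.07 and a downward test (adjusted p = 0.430). The ventricular cardiomyocyte markers, 11 of whose 13 genes stand in other lists too, averaged -0.17 ± 0.12 (SD) with 3 falls (adjusted p = 0.0639), and passed by fry and without the pig block. The muscle ubiquitin ligase FBXO32 fell by 1.13 ± 0.18 (SE) in a protein breakdown list with 1 rise and 4 falls among 22 (1 and 3 adjusted over the list alone, adjusted p = 0.806). Oxidative stress genes rose in 8 and fell in 4 of 22 cases (8 and 5 adjusted over the list alone, adjusted p = 0.141), with GPX1 at 0.65 ± 0.12 and TXNIP at -0.53 ± 0.09. Unfolded protein genes rose in 6 and fell in 2 of 19 cases (6 and 3 adjusted over the list alone) and hypoxia genes in 9 and 6 of 31, also adjusted over the list alone. Both had a median below 0 (-0.01) and a mean above it, and neither passed by camera or fry. Smooth muscle markers had 3 rises and 1 fall among 7 (3 and 2 adjusted over the list alone), with CNN1 at 1.74 ± 0.17, and resident macrophage markers 2 rises among 6 either way, with CD163 at 1.12 ± 0.14. Neither list passed camera. By fry the ion channel, oxidative stress and resident macrophage lists passed.

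Clock genes rose as a list in the control pigs over the whole course, with 3 rises among 8 either way and a mean of 0.35 ± 0.10 (SD, 5 of 5 pigs, adjusted p = 0.0241, and adjusted p = 0.119 with an estimated correlation). RORA stood at 0.65 ± 0.18 (SE) and ARNTL at 0.47 ± 0.13 there. In the shunt pigs ARNTL rose by 1.07 ± 0.12, NFIL3 by 1.20 ± 0.27 and BHLHE40 by 1.00 ± 0.20 while DBP fell by 0.29 ± 0.09. There the list mean (0.30) and median (-0.11) differed in sign and the list passed by fry but not by camera (adjusted p = 0.506). Glucocorticoid-induced genes had 9 rises and 3 falls among 19 in the shunt pigs, also adjusted over the list alone (adjusted p = 0.0859), and KLF15, a transcription factor of that list, stood at -1.22 ± 0.23. That list passed by fry and with the probe sets of a gene averaged. In the control pigs leukocyte adhesion genes rose in 6 and fell in 2 of 26 cases either way (mean 0.39 ± 0.14, adjusted p = 0.000383, and adjusted p = 0.178 with an estimated correlation). Matrix genes rose in 4 of 35 cases (5 adjusted over the list alone, mean 0.25 ± 0.17, adjusted p = 0.0171, and adjusted p = 0.616 with an estimated correlation), with THBS1 at 2.21 ± 0.31. Resident macrophage markers rose in 1 of 6 cases (2 adjusted over the list alone, mean 0.25 ± 0.23, adjusted p = 0.0241, and adjusted p = 0.386 with an estimated correlation). Interferon genes had 1 fall among 20 in the control pigs either way (XAF1, -0.42 ± 0.10). In the shunt pigs they had 2 rises (IFIT2, 0.45 ± 0.14, and TAP1, 0.35 ± 0.13) and 1 fall (RSAD2, -0.77 ± 0.18), of which only the fall passed adjusted over the list alone. Red cell markers averaged -0.70 ± 0.60 (SD) in the control pigs and 0.40 ± 0.53 in the shunt pigs, and lymphocyte markers -0.22 ± 0.10 and -0.03 ± 0.18. Neither list passed camera within an arm, while red cell markers, lower in 5 of 5 control pigs, passed by fry there.

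A shunt that unloads the ventricle might be thought to bring expression back toward baseline, which would show as a negative correlation across genes between the response to banding in the control pigs and the later change in the shunt pigs. That correlation was 0.19. Pig by pig it was 0.19, 0.39, 0.25 and 0.43 in shunt pigs 1, 2, 3 and 6 and -0.37 and -0.40 in shunt pigs 4 and 5, so a return in single pigs stays open. The same measure in the control pigs, against the response of the shunt pigs, was -0.23, 0.42, 0.09, -0.05 and 0.05.

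Other splits of the pigs were used to see whether chance could give as many calls. For the response at 120 min 1 of 100 splits drawn from 1024, the real one, reached 6964 (highest other 1577), so chance is excluded there. For the whole course in the shunt arm 1 of 32 reached 7815 (highest other 5468). That share is under 0.05 but is the smallest that 32 splits can give, so it argues against chance without excluding it. At baseline 2 of 100 splits drawn from 462 reached 5 calls, the real one and another that also gave 5. At an unadjusted p under 0.05 the real split had 2820 probe sets, also reached by 2 of 100 (highest other 3145). Both shares are under the planned 0.05. Since another split did as well, chance is still not called excluded for the baseline difference, and array set and arm cannot be told apart in it. In the control arm the 16 splits are too few for a share under 0.05: the whole course gave 2110 (highest other 0), and the later change 0 (highest other 2). Where the real count was 0 every split gave at least as many, so 32 of 32 for the later change in the shunt arm (highest other 50), 100 of 100 for the shunt effect (highest other 66) and 100 of 100 for the responses of the arms at 120 min (highest other 1) were fixed beforehand and say nothing about chance. At an unadjusted p under 0.05 the later change in the shunt arm had 2146 probe sets, reached by 5 of 32 splits (highest other 3692). The shunt effect had 737, reached by 66 of 100 (highest other 3438), and the responses at 120 min 1655, reached by 11 of 100 (highest other 2440), so chance is not excluded for these 3 counts. The single whole-course difference between the arms was matched by 9 of 100 splits, so that chance is not excluded for it either. The highest other there, 2342, came from setting shunt pigs 4 and 5 with control pigs 1, 3, 4 and 5 against the rest, which points to a structure of the samples that the arms do not follow.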
